A study of Mus musculus with 18 samples.

How the data were processed

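The series holds 18 Affymetrix GeneChip arrays of mouse spleen cells. The 6 samples, 2 each of interferon-producing killer dendritic cells (IKDC), conventional dendritic cells (cDC) and plasmacytoid dendritic cells (PDC), were each hybridised to the 3 array types of the U74 version 2 set (U74A, U74B and U74C). Per the series design, the 2 samples of a population were prepared separately. Whether they came from separate animals is not given in the sources used here. The p-values rest only on the spread between such samples, pooled over the 3 populations and moderated over probe sets. Part of that spread may be technical. The population and the replicate number were taken from the sample titles. How the cells were sorted is not given in the sources used here.

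Per the labels' protocols, total RNA was extracted with Trizol, purified on columns and amplified in a pair of rounds for small samples, and biotin-labelled antisense cRNA was hybridised. The deposited values are signal intensities on a linear scale that the authors made with GCOS 1.1.1 at its default settings and scaled per array to a target of 150, per the labels. The submitters' processing notes name MAS 5. The trimmed mean of every deposited array, leaving out 2% at each end, lay between 150.035 and 150.098. No detection calls were used here. The median signal per array was 51.7 to 87.3, and 47.2% to 60.5% of probe sets reached a signal of 60. Amplification in a pair of rounds shortens transcripts towards their 3' end, and the 3' to 5' ratio of the Gapdh control was 2.97 to 6.0 over the arrays. Scaling each array to one mean level assumes that total signal was alike in all samples, and a fold change is relative to that mean. The number of arrays limits the precision.

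Signals were used as log2(signal + 16), which understates the change of low genes. Array types were fitted separately because they were scaled separately, and levels are not compared between them. Control probe sets were left out (66 on each array type, 198 in all), and the 23285 of 36701 probe sets with a signal of 60 or more on at least 2 of the 6 arrays were tested, 7081 on U74A, 8402 on U74B and 7802 on U74C. Unspiked bacterial control probe sets had signals under 60 in 100% of values on U74A, 88.9% on U74B and 75.6% on U74C, with a highest value of 148.7, which makes the minimum of 60 a weaker bound on U74B and U74C. Each probe set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend) with all 3 populations in 1 model, which leaves 3 residual degrees of freedom before moderation. P-values were adjusted by the Benjamini-Hochberg method over all array types, with a threshold of 0.05. Where both arrays of a group were under 60 and the other group was above it, the fold is given as a bound, as at least N-fold. It is the geometric mean of the brighter group's 2 signals, with a signal under 60 taken as 60, over 60, and it can lie under the ratio of the arithmetic mean to 60.

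Gene names came from the platform annotation and were updated through gene identifiers to the names of a GRCm38.p6 gene table, from which no coordinates were used. Of 36701 probe sets 29131 paired with 1 symbol, 724 with several and 6846 with none listed, and 29044 symbols were updated while 87 were kept. Probe sets with several symbols named no gene. A gene with several probe sets was represented by the tested one with the highest mean signal, which gave 12193 genes, 4478 of them with several tested probe sets. Other probe sets of a gene can differ: the 2 further probe sets of H2-Aa did not pass in any comparison, and of the 2 further ones of Irf7 1 passed in each comparison with PDC. The further probe set of Gimap4, Txk and Il2rb did not pass in either comparison of IKDC. In IKDC versus cDC neither that of Wdfy4 nor the 2 of Ms4a6c passed. Further probe sets of some other genes named below did not pass either. Klrb1c, Itga2, Ly6c1 and Gapdh, which the naming rule lists, had no tested probe set with 1 symbol and are not analysed here.

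Before the data were examined, the samples, the tests, the alternatives, 21 gene lists and the rule for naming genes were fixed. The rule names, in each comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 difference among those past the threshold, with both samples of a group above both of the other and a mean of at least 200 in the higher group. It also names up to 4 members of each list with the smallest adjusted p past the threshold, or up to 2 with the highest mean signal where none passes, the 8 leading genes highest in each population and a fixed set of marker genes. From these the text gives the leading genes and examples. Gene lists were tested with camera at the preset inter-gene correlation of 0.01, on 1 probe set per gene over the 3 array types joined by sample, and adjusted over 63 tests, 21 lists in 3 comparisons. Of the 63 tests 42 passed, and 3 also passed with an estimated correlation: conventional dendritic cell genes in IKDC versus cDC, and plasmacytoid genes in PDC versus cDC and in IKDC versus PDC. Among called lists p rose also where the estimated correlation lay under 0.01, and the lost calls are no measure of gene correlation alone. With fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, 32 passed. A list of pancreas genes was written later. It was set against 10000 random lists of the same size matched on mean signal.

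Overlaps between comparisons that share samples were set beside 100 simulations of unchanged groups. The fit was tested on simulated data for IKDC versus cDC. These used the means of the 23285 probe sets, with spreads drawn from the distribution that limma had fitted to them. Of 200 changed probe sets it recovered 0% at 2-fold, 31% at 4-fold with 6 false calls and 70% at 8-fold with 10 false calls, and with nothing changed it made 0 false calls. Such data meet the assumptions of the fit, and the result does not show the error rate on the real arrays. Alternatives covered the pseudocount (1 and 64), the signal filter (none, or 200), quantile normalization and median centring between arrays, leaving out probe sets suffixed f, s, i, r or g, the samples in the fit, the trend, the family of tests, a replicate block, leaving out each sample, the threshold, the set test and the probe set of a gene. Leaving out 1 sample leaves 1 in its group and fewer residual degrees of freedom. A call can then end although the log2 difference hardly moves, and such an end alone does not show that a result rests on that sample. No 2 samples shared over 0.585% of their exact values on an array type. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.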

Results

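Transcript levels were compared in 3 populations of mouse spleen cells named in the sample labels: interferon-producing killer dendritic cells (IKDC), plasmacytoid dendritic cells (PDC) and conventional dendritic cells (cDC), the population the submitters used as control. Plasmacytoid dendritic cells are known for type I interferon production, and conventional dendritic cells for antigen presentation to T cells. The labels list 2 samples per population, prepared separately, and each was hybridised to 3 Affymetrix array types (U74A, U74B and U74C), giving 18 arrays. The deposited signals had a median per array between 51.7 and 87.3, and the number of arrays limits the precision. Across probe sets, which are not independent replicates, samples of 1 population correlated at 0.785 to 0.953 and samples of different populations at 0.707 to 0.817. The highest correlation between populations, 0.817 on U74C, joined PDC replicate 2 to IKDC replicate 2 and exceeded the 0.809 between the PDC replicates there. The 3' to 5' signal ratio of the Gapdh control on U74A, which RNA breakdown and shortening in amplification raise, was 3.34 and 3.59 in the IKDC samples and 3.19 in PDC replicate 2. It was 4.74 and 4.13 in the cDC samples and 6.0 in PDC replicate 1. Signals below are the mean ± SD of the 2 samples, log2 differences are estimate ± SE, and p-values are from limma, adjusted by the Benjamini-Hochberg method over 23285 probe sets. No genome position is given because the files name probe sets only.

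The series compared IKDC with cDC to profile a population that its name describes as both killer and dendritic. Transcripts of killing and of natural killer (NK) cell receptors were higher in IKDC. Ncr1, which encodes the NK receptor NKp46, had a signal of 1483 ± 177 in IKDC against 39.5 ± 0.919 in cDC, at least 24.6-fold higher against the signal minimum of 60 (limma adjusted p = 1.79e-05). Gzma, encoding the granule protease granzyme A, stood at 3926 ± 475 against 179 ± 62.1, and Prf1, encoding the pore-forming perforin, at 839 ± 18.2 against 85.5 ± 7.5. Ctsw, a protease of cytotoxic lymphocytes, was at least 25.4-fold higher, and Nkg7, a granule protein gene, differed by 4.06 ± 0.26 log2 units. Gzmb rose by 2.70 ± 0.40 log2 units to a signal of 664 ± 152. Ifng, encoding interferon gamma, had a signal of 203 ± 36.6 in IKDC and 37.9 ± 1.49 in cDC (2.02 ± 0.41 log2 units, limma adjusted p = 0.0132). That call ended when either cDC or either IKDC sample was left out, while the log2 difference stayed at 1.84 to 2.19.

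Of 18 measured cytotoxic effector genes, 8 rose and none fell (9 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 2.69e-08 with the preset correlation and adjusted p = 0.1 with an estimated correlation. Among 22 NK cell receptor and marker genes, 17 rose (17 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 1.62e-15 with the preset correlation and adjusted p = 0.0933 with an estimated correlation. Klra3, of the Ly49 receptor family, stood at 2995 ± 174 against 188 ± 21.9, and Klrd1, encoding CD94, at 3000 ± 71.5 against 361 ± 1.7. Klrk1, encoding NKG2D, differed by 2.89 ± 0.25 log2 units and Il2rb, a chain of the interleukin 2 and 15 receptors, by 2.94 ± 0.28. Ly49 and granzyme genes have close paralogs, and a probe set can take up signal from several of them. In the list of NK lineage transcription and signalling genes, 9 of 20 rose (11 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 6.53e-08 with the preset correlation and adjusted p = 0.121 with an estimated correlation. The T-box factor gene Eomes was at least 21-fold higher, the kinase gene Txk at least 21.4-fold and the adaptor gene Sh2d2a at least 18.8-fold. Samd3 differed by 4.50 ± 0.32 log2 units. Among 15 T cell marker genes 7 rose (9 higher and 2 lower when adjusted over the list alone), with camera adjusted p = 0.00028 with the preset correlation and adjusted p = 0.202 with an estimated correlation. They included Cd2 (4.26 ± 0.45 log2 units), Cd27 (2.88 ± 0.37) and Thy1 (at least 5.57-fold), which NK cells also express, and Cd28 (at least 5.54-fold), a co-stimulatory receptor gene of T cells.

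Antigen presentation and conventional dendritic cell transcripts were lower in IKDC than in cDC. H2-Ab1, which encodes an MHC class II chain, had a signal of 519 ± 195 in IKDC and 8387 ± 860.1 in cDC (-4.02 ± 0.31 log2 units, limma adjusted p = 3.37e-05). H2-Aa stood at 2152 ± 837 against 18340 ± 4717, and the invariant chain gene Cd74 at 1030 ± 114 against 12260 ± 545. These signals in IKDC remained far above the minimum of 60. Of 17 genes of MHC class II and antigen processing, 13 fell and none rose (0 higher and 15 lower when adjusted over the list alone), with camera adjusted p = 2.13e-18 with the preset correlation and adjusted p = 0.123 with an estimated correlation. Of 32 conventional dendritic cell genes, 19 fell and none rose (1 higher and 23 lower when adjusted over the list alone), a list called with camera adjusted p = 3.77e-18 with the preset correlation and adjusted p = 0.0409 with an estimated correlation. Cadm1 differed by -4.18 ± 0.26 log2 units, Wdfy4, required for cross-presentation, by -4.28 ± 0.23 and the transcription factor gene Batf3 by -3.55 ± 0.32. The cytokine receptor gene Flt3 fell from 2547 ± 224 in cDC to 269.5 ± 12.2, and Cd8a was at least 8.38-fold lower. Itgax, which encodes CD11c, did not pass the test at 1304 ± 77.8 in IKDC and 2085 ± 748 in cDC (limma adjusted p = 0.316). Zbtb46, at 21.3 ± 0.495 against 105 ± 31.5, did not pass either (limma adjusted p = 0.0842), but passed without PDC replicate 1 (adjusted p = 0.0364) or PDC replicate 2 (adjusted p = 0.0304). It passed too with a pseudocount of 64 (limma adjusted p = 0.0479), only the 2 groups in the fit (0.0243), no trend (0.0386) and adjustment within each array type (0.0485). Ptprc, the leukocyte antigen CD45, had 3141 ± 91.9 against 1793 ± 871 (limma adjusted p = 0.201), and Actb 8417 ± 1269 against 3364 ± 2992 (limma adjusted p = 0.106, or adjusted p = 0.00325 without cDC replicate 1).

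The decreases taken by the naming rule in IKDC against cDC were in Sirpb1a (-6.53 ± 0.46 log2 units), the macrophage elastase gene Mmp12 (at least 37.8-fold lower), Plbd1 (-5.42 ± 0.35), the apoptosis gene Pmaip1 (-5.06 ± 0.47), Adgre4 (-4.98 ± 0.63), the co-stimulator gene Cd86 (at least 17.2-fold lower), Il1b (at least 23.6-fold lower) and Ms4a6c (-4.85 ± 0.64). At least 1 IKDC signal of Sirpb1a and Ms4a6c on U74C, and of Pmaip1, Adgre4 and Cd86 on U74B, lay under the highest unspiked bacterial control of the array type (148.7 and 122.7), and the sizes and order of these differences are not secure. Of 22 monocyte and macrophage marker genes, 16 fell and none rose (0 higher and 20 lower when adjusted over the list alone), with camera adjusted p = 8.82e-16 with the preset correlation and adjusted p = 0.0987 with an estimated correlation. Csf1r, the receptor for macrophage colony stimulating factor, stood at 68.8 ± 9.19 against 1322 ± 119. Of 19 co-stimulation and maturation genes, 6 fell (2 higher and 10 lower when adjusted over the list alone), with camera adjusted p = 6.8e-05 with the preset correlation and adjusted p = 0.242 with an estimated correlation. Cd274, encoding the inhibitory ligand PD-L1, differed by -2.64 ± 0.32 log2 units. Among 23 Toll-like receptor and innate sensing genes, 1 rose and 9 fell (3 higher and 14 lower when adjusted over the list alone), with camera adjusted p = 0.000349 with the preset correlation and adjusted p = 0.158 with an estimated correlation. Ly86, a partner of the receptor CD180, differed by -3.54 ± 0.26 log2 units and Tlr2 by -1.84 ± 0.28. Camp and Ltf were the 2 genes that fell among 10 neutrophil and granule markers (0 higher and 4 lower when adjusted over the list alone), with camera adjusted p = 0.000744 with the preset correlation and adjusted p = 0.312 with an estimated correlation. Both of those gene calls ended without cDC replicate 2, at limma adjusted p of 0.259 and 0.277, and without either IKDC sample, at 0.126 to 0.195. The Ltf call also ended without cDC replicate 1, at limma adjusted p of 0.051. The Camp call ended as well after quantile normalization (limma adjusted p = 0.0623), without the filter (0.052), without the intensity trend (0.071) and with the mean of probe sets (0.0585), and the Ltf call with a pseudocount of 1 (0.0749) and the mean of probe sets (0.0549). With a filter at 200 the neutrophil list reached adjusted p = 0.0583, and without the trend Tlr2 reached limma adjusted p = 0.061.

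Erythroid transcripts were higher in IKDC, with 12760 ± 987 for the haemoglobin gene Hba-a1 against 932 ± 589 in cDC, and 1769 ± 307 against 158 ± 47.2 for the carbonic anhydrase gene Car2. Of 12 erythroid and platelet marker genes 7 rose and none fell (7 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 1.49e-07 with the preset correlation and adjusted p = 0.123 with an estimated correlation. The immunoglobulin gene Igha stood at 5057 ± 1205 against 208 ± 25.8 (4.48 ± 0.39 log2 units), with 4544 ± 2729 in PDC, while the other 2 probe sets of Igha did not pass. Among 17 B cell marker genes 4 rose and 1 fell (8 higher and 3 lower when adjusted over the list alone), with camera adjusted p = 0.0478 with the preset correlation and adjusted p = 0.473 with an estimated correlation. A list of 34 pancreas genes, written after the data were first examined, had 19 measured members, of which 7 rose and none fell in IKDC. Their median log2 difference was 1.44. Several further list calls were weaker. Of 33 cell cycle genes none passed by limma, and 11 had an unadjusted p under 0.05 (6 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 0.00586 with the preset correlation and adjusted p = 0.278 with an estimated correlation. Of 16 genes of the MHC class I pathway 3 fell (0 higher and 3 lower when adjusted over the list alone), with camera adjusted p = 0.0122 with the preset correlation and adjusted p = 0.263 with an estimated correlation, and the nonclassical gene H2-M3 differed by -1.83 ± 0.26 log2 units. Of 28 immediate early and heat shock genes 1 rose and 6 fell (2 higher and 7 lower when adjusted over the list alone), with camera adjusted p = 0.0113 with the preset correlation and adjusted p = 0.454 with an estimated correlation. Of 32 dendritic cell lineage transcription factor genes 6 rose, among them Myb (3.25 ± 0.44 log2 units, a size not secure with 1 cDC signal under the 45.2 that unspiked controls reached on U74A), and 9 fell, among them Spi1 (-3.09 ± 0.32) and Cbfa2t3 (-2.93 ± 0.41), with 8 higher and 11 lower when adjusted over the list alone. That list had camera adjusted p = 0.0478 with the preset correlation and adjusted p = 0.213 with an estimated correlation. Leaving out 1 sample ended some of these list calls by camera. The MHC class I pathway reached adjusted p = 0.0989 without cDC replicate 2, and the cell cycle and the immediate early and heat shock lists each reached adjusted p = 0.0736 without IKDC replicate 2. The B cell list reached adjusted p = 0.0694 without cDC replicate 1, adjusted p = 0.0579 without cDC replicate 2, adjusted p = 0.449 without IKDC replicate 1, adjusted p = 0.0635 without PDC replicate 1 and adjusted p = 0.0622 without PDC replicate 2. The lineage factor list reached adjusted p = 0.0675 without cDC replicate 1, adjusted p = 0.0981 without cDC replicate 2, adjusted p = 0.0736 without IKDC replicate 2, adjusted p = 0.0564 without PDC replicate 1 and adjusted p = 0.0606 without PDC replicate 2. Other settings ended list calls too. The B cell list reached adjusted p = 0.052 with a pseudocount of 64, 0.142 with a filter at 200, 0.0736 after median centring, 0.0642 with only the 2 groups, 0.0625 without the trend and 0.0613 with the mean of probe sets. The lineage factor list reached adjusted p = 0.0908 without the filter, 0.0522 with only the 2 groups and 0.0748 without the trend. The cell cycle list reached adjusted p = 0.051 with a filter at 200, and the MHC class I pathway adjusted p = 0.0736 on U74A alone.

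Chemokine genes moved both ways in IKDC, with 6 of 26 chemokine and homing receptor genes higher and 6 lower (7 higher and 9 lower when adjusted over the list alone), and the list did not pass, with camera adjusted p = 0.67 with the preset correlation and adjusted p = 0.719 with an estimated correlation. Ccl5 reached 11930 ± 1221 against 1568 ± 252 in cDC, while Cxcl9 was at least 5.28-fold lower. Plasmacytoid genes moved both ways too, with 3 of 27 higher and 7 lower in IKDC (7 higher and 7 lower when adjusted over the list alone), and the list did not pass, with camera adjusted p = 0.706 with the preset correlation and adjusted p = 0.719 with an estimated correlation.

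In all, 1305 of 23285 probe sets passed an adjusted p of 0.05 between IKDC and cDC by limma, 625 higher and 680 lower in IKDC, representing 427 and 496 genes. The unadjusted p was under 0.05 for 4411 probe sets. The median log2 difference of all tested probe sets was -0.01, with a median SE of 0.431, and no called difference was below 0.948 in size. The count fell to 617 without cDC replicate 1 (292 higher, 325 lower), 610 without cDC replicate 2 (341 and 269), 593 without IKDC replicate 1 (235 and 358) and 598 without IKDC replicate 2 (214 and 384). The p-values rest on the spread between 2 separately prepared samples per population, pooled over the 3 populations and moderated over probe sets. Moderation raised the 3 residual degrees of freedom to a median of 10.5.

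**Figure D1:**
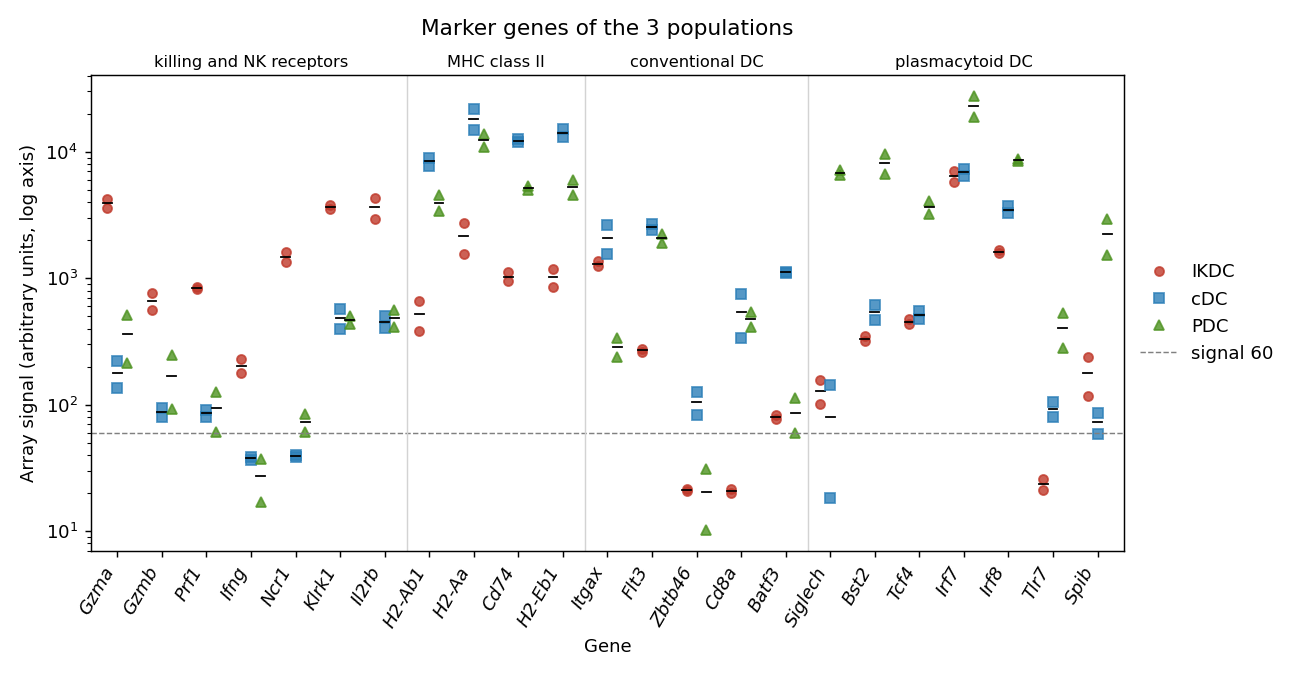
Array signal (arbitrary units, log axis) of marker genes in each IKDC (circles), cDC (squares) and PDC (triangles) sample, with the mean of the 2 samples as a bar and the signal minimum of 60 dashed. The granzyme, perforin and NK receptor genes lie highest in IKDC, the MHC class II genes lowest in IKDC, and Siglech, Bst2, Tcf4, Irf7 and Irf8 highest in PDC.

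The comparison of PDC with cDC asks what sets the plasmacytoid population apart from the control. Known plasmacytoid genes were higher in PDC. Siglech, encoding a sialic acid binding lectin of these cells, had a signal of 6852 ± 478 in PDC and 80.6 ± 88 in cDC (6.54 ± 0.57 log2 units, limma adjusted p = 0.000236). Bst2 stood at 8114 ± 2059 against 538 ± 101, and the transcription factor genes Tcf4 at 3663 ± 626 against 514 ± 55.7 and Spib at 2235 ± 1003 against 72.7 ± 19.7. Of 27 measured plasmacytoid dendritic cell genes, 23 rose and none fell (26 higher and 0 lower when adjusted over the list alone), a list called with camera adjusted p = 8.38e-34 with the preset correlation and adjusted p = 0.0288 with an estimated correlation. Irf7, a factor of interferon induction, rose by 1.71 ± 0.25 log2 units (limma adjusted p = 0.00364), or adjusted p = 0.0522 without PDC replicate 2 and adjusted p = 0.107 without the intensity trend. Irf8 stood at 8673 ± 238 against 3490 ± 312 (limma adjusted p = 0.0157), a call that ended without the trend (limma adjusted p = 0.0539). It also ended without either cDC or either PDC sample, where the log2 difference was 1.22 to 1.4. Tlr7, a sensor of single-stranded RNA, stood at 404 ± 176 against 93 ± 17.6 (limma adjusted p = 0.0168). That call ended without cDC replicate 1, cDC replicate 2 or PDC replicate 1, at limma adjusted p of 0.128, 0.078 and 0.0927. Tlr9, with 101 ± 49 against 39.1 ± 5.37, did not pass (limma adjusted p = 0.394).

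The increases taken by the naming rule in PDC were in D13Ertd608e (at least 82.8-fold), Siglech, the kallikrein genes Klk1 (6.48 ± 0.29 log2 units), Klk1b5 (at least 38.5-fold), Klk1b21 (5.78 ± 0.29) and Klk1b22 (5.24 ± 0.28), Cd8b1 (at least 40.9-fold) and the cathepsin gene Ctsl (5.49 ± 0.31). The kallikrein genes are near-identical paralogs, and a probe set can take up signal from several of them. Cox6a2 rose by 5.10 ± 0.29 log2 units and the chemokine receptor gene Ccr9 by 3.01 ± 0.33. At least 1 cDC signal of Siglech and Ccr9 on U74B and of Klk1b21 on U74C lay under the highest unspiked bacterial control there (122.7 and 148.7), and the sizes of these differences are not secure. Cd8a did not pass, with 477 ± 95.3 against 545 ± 296 (limma adjusted p = 0.955). Among 15 T cell marker genes 4 rose and 1 fell (5 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 0.00768 with the preset correlation and adjusted p = 0.263 with an estimated correlation. Il7r, the interleukin 7 receptor, rose by 3.21 ± 0.35 log2 units. The list call ended without cDC replicate 2 or PDC replicate 1, and without suffixed probe sets (camera adjusted p = 0.0669). Of 27 genes of secretion and the unfolded protein response 3 rose (7 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 0.00105 with the preset correlation and adjusted p = 0.242 with an estimated correlation. Xbp1, a regulator of secretion, rose by 2.08 ± 0.33 log2 units (limma adjusted p = 0.00446, or adjusted p = 0.0549 without cDC replicate 2). Of 28 interferon response genes 4 rose and 2 fell (5 higher and 2 lower when adjusted over the list alone), with camera adjusted p = 0.0248 with the preset correlation and adjusted p = 0.208 with an estimated correlation. That list reached adjusted p = 0.0769 without cDC replicate 2 and adjusted p = 0.124 without PDC replicate 2, and adjusted p = 0.0908 without the filter and 0.138 with a filter at 200.

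Conventional dendritic cell, myeloid and activation transcripts were lower in PDC than in cDC. Of 32 conventional dendritic cell genes 12 fell and 3 rose (4 higher and 20 lower when adjusted over the list alone), with camera adjusted p = 3.76e-09 with the preset correlation and adjusted p = 0.0909 with an estimated correlation. Itgax fell from 2085 ± 748 to 289 ± 70.9 and Batf3 by 3.52 ± 0.32 log2 units, while Flt3 did not pass at 2069 ± 213 against 2547 ± 224 (limma adjusted p = 0.695). Zbtb46 had 20.6 ± 14.5 against 105 ± 31.5 (limma adjusted p = 0.0915, or adjusted p = 0.0441 without the trend). The decreases taken by the naming rule were in Sirpb1a (-5.40 ± 0.46 log2 units), Rtn1 (at least 24.3-fold lower), Mmp12 (-5.00 ± 0.39), Rasgef1b (-4.93 ± 0.82), Adam8 (at least 10.8-fold lower), Il1b (at least 23.6-fold lower), the maturation marker Cd83 (-4.36 ± 0.53) and Plbd1 (-4.32 ± 0.35). The Rasgef1b call ended without the trend (limma adjusted p = 0.0725). It also ended without cDC replicate 1 or cDC replicate 2, where the log2 difference was -5.14 and -4.73. Of 22 monocyte and macrophage genes 9 fell (2 higher and 15 lower when adjusted over the list alone), with camera adjusted p = 4.93e-08 with the preset correlation and adjusted p = 0.129 with an estimated correlation, among them the complement gene C1qa (at least 5.85-fold lower). Of 19 co-stimulation genes 6 fell (0 higher and 11 lower when adjusted over the list alone), with camera adjusted p = 2.69e-08 with the preset correlation and adjusted p = 0.172 with an estimated correlation, among them Traf1 (-2.90 ± 0.29 log2 units) and Cd274 (-3.32 ± 0.32). The sizes for Sirpb1a, Rtn1 and Rasgef1b on U74C and Cd274 on U74B are not secure, since at least 1 PDC signal of each lay under the highest unspiked bacterial control there (148.7 and 122.7). The same holds for 1 PDC signal each of Mmp12 and Cd83 on U74A, where that control reached 45.2. Of 28 immediate early and heat shock genes 9 fell and none rose (0 higher and 15 lower when adjusted over the list alone), with camera adjusted p = 2.25e-08 with the preset correlation and adjusted p = 0.208 with an estimated correlation. Nr4a1, an early gene of receptor stimulation, stood at 143 ± 13.1 against 2643 ± 414, and Egr2 was at least 12.3-fold lower.

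MHC class II genes were lower in PDC too. Of 17 members 6 fell and none rose (0 higher and 9 lower when adjusted over the list alone), with camera adjusted p = 2.45e-07 with the preset correlation and adjusted p = 0.242 with an estimated correlation. H2-Ob, a modulator of peptide loading, differed by -2.40 ± 0.35 log2 units (limma adjusted p = 0.00278, or adjusted p = 0.0543 without cDC replicate 2). H2-Ab1 with 3965 ± 827 against 8387 ± 860.1 did not pass (limma adjusted p = 0.0977, or adjusted p = 0.0335 with a replicate block). Nor did H2-Aa with 12410 ± 2038 against 18340 ± 4717 (limma adjusted p = 0.535). Of 23 Toll-like receptor and sensing genes 1 rose and 5 fell (2 higher and 8 lower when adjusted over the list alone), with camera adjusted p = 0.0478 with the preset correlation and adjusted p = 0.273 with an estimated correlation. Of 12 cytokine genes 2 fell, Il1b and Tnf (1 higher and 3 lower when adjusted over the list alone), with camera adjusted p = 0.0192 with the preset correlation and adjusted p = 0.263 with an estimated correlation. Tnf had 200.4 ± 114 in PDC and 581 ± 161 in cDC (limma adjusted p = 0.0496), and its call ended without any 1 of 5 samples. This gave limma adjusted p of 0.31 without cDC replicate 1, 0.116 without cDC replicate 2, 0.209 without PDC replicate 2, 0.0745 without IKDC replicate 1 and 0.0739 without IKDC replicate 2. It also ended after quantile normalization (limma adjusted p = 0.0796) and median centring (limma adjusted p = 0.0511), and with a pseudocount of 1, no filter, only the 2 groups, no trend or the mean of probe sets, at limma adjusted p of 0.0613 to 0.102. Of 26 chemokine and homing receptor genes 2 rose and 5 fell (2 higher and 9 lower when adjusted over the list alone), with camera adjusted p = 0.013 with the preset correlation and adjusted p = 0.208 with an estimated correlation. Cxcr3 rose by 2.45 ± 0.27 log2 units. Leaving out 1 sample ended the calls of these 3 lists. The sensing list reached adjusted p = 0.263 without cDC replicate 2 and adjusted p = 0.124 without PDC replicate 1. It reached adjusted p = 0.0575 with a pseudocount of 1, 0.0645 with a filter at 200, 0.0625 without the trend, 0.0898 with the mean of probe sets and 0.934 on U74A alone. The cytokine list reached adjusted p = 0.0768 without cDC replicate 2 and adjusted p = 0.0948 without PDC replicate 2, and adjusted p = 0.191 without the filter. The chemokine list reached adjusted p = 0.0832 without PDC replicate 2, 0.0694 with a filter at 200 and 0.0625 on U74A alone.

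Killing and NK receptor genes, as lists, did not pass in this comparison. Of 18 cytotoxic effector genes 1 rose in PDC and 2 fell (3 higher and 4 lower when adjusted over the list alone), with camera adjusted p = 0.773 with the preset correlation and adjusted p = 0.828 with an estimated correlation. Of 22 NK receptor and marker genes 2 rose and 1 fell (4 higher and 3 lower when adjusted over the list alone), with camera adjusted p = 0.4 with the preset correlation and adjusted p = 0.611 with an estimated correlation. Gzma had 363 ± 209.7 in PDC against 179 ± 62.1 in cDC (limma adjusted p = 0.32), Gzmb 170 ± 109 against 87.5 ± 9.97 (limma adjusted p = 0.475), Ncr1 72.6 ± 16.5 against 39.5 ± 0.919 (limma adjusted p = 0.332) and Ifng 27.2 ± 14.6 against 37.9 ± 1.49 (limma adjusted p = 0.781). Erythroid transcripts were higher in PDC as well, with 6 of 12 markers called and none lower (7 higher and 0 lower when adjusted over the list alone), and camera adjusted p = 3.9e-08 with the preset correlation and adjusted p = 0.121 with an estimated correlation. Hba-a1 stood at 14590 ± 9230 and Car2 at 656 ± 73.2. Of the 19 measured pancreas genes 1 rose and none fell, with a median log2 difference of 0.61. Cell cycle genes as a list lay lower in PDC although none of 33 passed by limma, with 9 at an unadjusted p under 0.05 (0 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 0.00223 with the preset correlation and adjusted p = 0.263 with an estimated correlation. By limma 849 probe sets passed between PDC and cDC, 402 higher and 447 lower in PDC, for 274 and 335 genes, and 3472 had an unadjusted p under 0.05. The count fell to 349 without cDC replicate 1 (197 higher, 152 lower) and to 327 without cDC replicate 2 (221 and 106). Without PDC replicate 2 it was 591, with 214 higher and 377 lower.

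Setting IKDC against PDC, a comparison that follows from the 3 groups, showed 2 opposite blocks of genes. NK and cytotoxic transcripts were higher in IKDC and plasmacytoid transcripts higher in PDC. Of 22 NK receptor and marker genes 17 were higher in IKDC (17 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 5.75e-17 with the preset correlation and adjusted p = 0.0933 with an estimated correlation. Of 18 cytotoxic effectors 10 were higher (10 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 3.31e-10 with the preset correlation and adjusted p = 0.0959 with an estimated correlation, and of 20 NK lineage genes 8 were higher (10 higher and 1 lower when adjusted over the list alone), with camera adjusted p = 3.18e-07 with the preset correlation and adjusted p = 0.121 with an estimated correlation. Ctla2b was at least 18.2-fold higher in IKDC, Eomes at least 21-fold and Fzd5 at least 7.53-fold, a less secure bound because unspiked controls reached 122.7 on U74B. The sizes for Cd2 and Txk are not secure either, with 1 PDC signal each under the 45.2 that such controls reached on U74A. Differences were 4.30 ± 0.30 log2 units for Klra3, 4.26 ± 0.45 for Cd2, 4.25 ± 0.48 for Txk, 4.20 ± 0.32 for Samd3 and 4.09 ± 0.30 for Ncr1. Prf1 differed by 3.03 ± 0.34 log2 units and Gzma by 3.49 ± 0.39. Ifng was at least 3.36-fold higher in IKDC (2.38 ± 0.41 log2 units, limma adjusted p = 0.00546). The Ifng call ended without IKDC replicate 1 or IKDC replicate 2, where the log2 difference was 2.2 and 2.55. Itgax was also higher in IKDC, by 2.13 ± 0.31 log2 units, and so was the transcriptional regulator gene Id2, by 3.29 ± 0.30. Of 33 cell cycle genes 6 were higher in IKDC (15 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 2.25e-08 with the preset correlation and adjusted p = 0.134 with an estimated correlation, and Stmn1, which regulates microtubules, differed by 2.34 ± 0.33 log2 units. Of 28 immediate early genes 5 were higher in IKDC (6 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 0.00187 with the preset correlation and adjusted p = 0.374 with an estimated correlation. Nr4a1 differed by 3.04 ± 0.29 log2 units. That list call ended without IKDC replicate 1 (adjusted p = 0.0539) or PDC replicate 2 (adjusted p = 0.116).

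In the other direction, 21 of 27 plasmacytoid genes were lower in IKDC than in PDC and none higher (0 higher and 24 lower when adjusted over the list alone), a list called with camera adjusted p = 8.65e-31 with the preset correlation and adjusted p = 0.0288 with an estimated correlation. The differences taken by the naming rule were in D13Ertd608e (-5.67 ± 0.35 log2 units), Siglech (-5.59 ± 0.57), Klk1 (-5.34 ± 0.29), Klk1b21 (-5.07 ± 0.29), Upb1 (-5.05 ± 0.31), Cadm1 (-5.01 ± 0.26), Ctsl (-4.78 ± 0.31) and Klk1b1 (-4.78 ± 0.27). At least 1 IKDC signal of Siglech and Upb1 lay under the highest unspiked bacterial control of U74B (122.7), and their sizes are not secure. Bst2 differed by -4.52 ± 0.26 log2 units, Tcf4 by -2.96 ± 0.24, Irf8 by -2.41 ± 0.26 and Irf7 by -1.83 ± 0.25, and Tlr7 was at least 6.41-fold lower in IKDC. Without the intensity trend Irf7 reached limma adjusted p = 0.0787. MHC class II genes were lower in IKDC than in PDC in 11 of 17 cases (0 higher and 12 lower when adjusted over the list alone), with camera adjusted p = 8.68e-12 with the preset correlation and adjusted p = 0.173 with an estimated correlation. H2-Ab1 differed by -2.93 ± 0.31 log2 units and Cd74 by -2.31 ± 0.26. Of 32 conventional dendritic cell genes 3 were higher and 9 lower in IKDC (4 higher and 13 lower when adjusted over the list alone), with camera adjusted p = 4.7e-05 with the preset correlation and adjusted p = 0.1 with an estimated correlation. Cd209a, a C-type lectin gene, stood at 5439 ± 850 in PDC against 189 ± 32.3 in IKDC. Of 22 monocyte and macrophage genes 4 were lower (0 higher and 4 lower when adjusted over the list alone), with camera adjusted p = 4.7e-05 with the preset correlation and adjusted p = 0.197 with an estimated correlation, among them Mpeg1 (-4.59 ± 0.37 log2 units) and Cd68 (-3.28 ± 0.28). Of 28 interferon response genes 2 were higher and 5 lower in IKDC (2 higher and 9 lower when adjusted over the list alone), with camera adjusted p = 0.000123 with the preset correlation and adjusted p = 0.121 with an estimated correlation. The secretory list, with 3 of 27 lower (0 higher and 5 lower when adjusted over the list alone), had camera adjusted p = 0.00105 with the preset correlation and adjusted p = 0.242 with an estimated correlation, or adjusted p = 0.069 by camera without PDC replicate 2. Xbp1 differed by -2.40 ± 0.33 log2 units. The neutrophil list had no called member by limma of 10, and 0 at an unadjusted p under 0.05 (0 higher and 0 lower when adjusted over the list alone), with camera adjusted p = 0.0362 with the preset correlation and adjusted p = 0.473 with an estimated correlation. Its call ended without IKDC replicate 1 or PDC replicate 1. By camera it reached adjusted p = 0.082 without suffixed probe sets, adjusted p = 0.31 with a filter at 200 and adjusted p = 0.115 on U74A alone. By limma 1036 probe sets passed, 480 higher and 556 lower in IKDC, for 331 and 386 genes, and 3367 had an unadjusted p under 0.05. The count fell to 506 without IKDC replicate 1 (184 higher, 322 lower) and 493 without IKDC replicate 2 (186 and 307). Without PDC replicate 2 it was 793, with 451 higher and 342 lower.

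**Figure D2:**
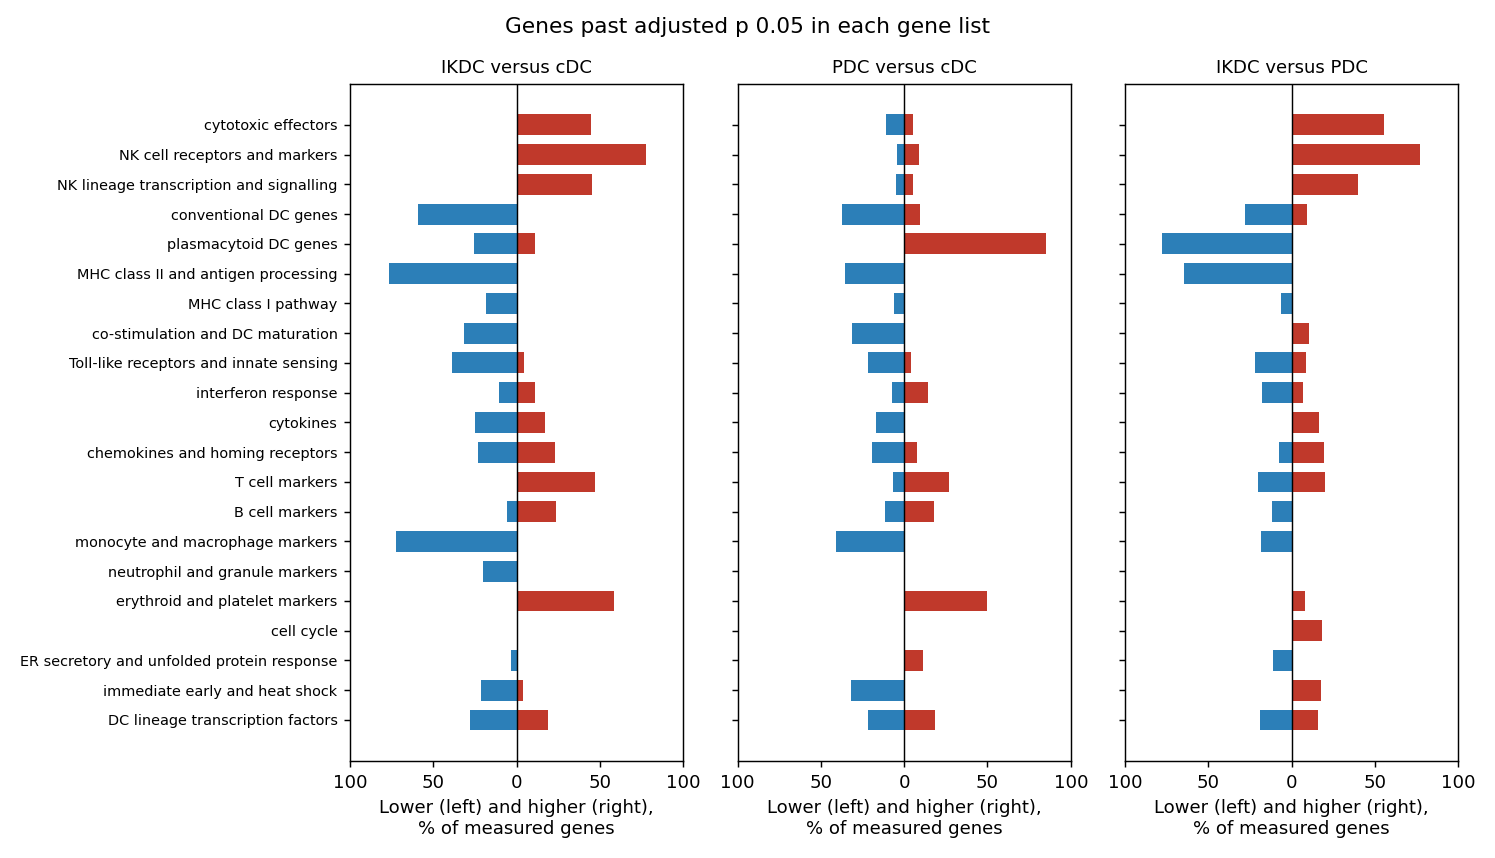
Share of the measured genes of each of 21 gene lists that passed a limma adjusted p of 0.05 in the 3 comparisons, with genes higher in the first-named population to the right and lower ones to the left (percent of measured genes). NK receptor genes lie to the right in both comparisons of IKDC, and plasmacytoid genes to the right in PDC versus cDC and to the left in IKDC versus PDC.

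Each population had genes that were higher in it than in both others. In IKDC these were led by Eomes, Cd2, Txk, Samd3, Ctla2b, Ncr1, Gimap4 and Fzd5. The further probe set of Txk and that of Gimap4 did not pass against cDC or PDC. Gimap4, a GTPase gene of lymphocytes, stood at 5274 ± 137 in IKDC, 319 ± 22.8 in cDC and 314 ± 121 in PDC, and Fzd5, a Wnt receptor gene, at 456 ± 82.3, 14.7 ± 7.14 and 12.1 ± 7.14. In PDC they were led by D13Ertd608e, Siglech, Klk1, Klk1b21, Ctsl, Klk1b1, Havcr1 and Klk1b5, with Ctsl at 3607 ± 708 in PDC, 65.3 ± 20.2 in cDC and 115 ± 21.9 in IKDC. Havcr1 stood at 8533 ± 2770, 242 ± 70.7 and 297 ± 34.9 in the same order. In cDC they were led by Sirpb1a, Mmp12, Adam8, Il1b, Rtn1, Plbd1, Cd86 and Atf3. Il1b, encoding interleukin 1 beta, stood at 1431 ± 267 in cDC, 33.5 ± 11.9 in IKDC and 43.4 ± 16 in PDC. The stress gene Atf3 stood at 7483 ± 433, 442 ± 326 and 619.7 ± 672. The log2 differences of Atf3 from cDC were -4.24 in IKDC and -4.15 in PDC. Both calls ended without cDC replicate 2, where the differences were -4.18 and -4.09. In PDC the call also ended without cDC replicate 1, at -4.21. The call of Cd86 between PDC and cDC ended without cDC replicate 1 or cDC replicate 2, where the log2 difference was -4.28 and -4.05.

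By limma 238 probe sets for 167 genes were highest in IKDC, 197 for 143 genes in PDC and 267 for 204 genes in cDC. Independent lists of these lengths would share 12.9, 9.6 and 13.1 probe sets, and 100 simulations of unchanged groups gave a mean of 0.03, 0.03 and 0.02, with a highest value of 1 in each. Unchanged groups give almost no calls, and those simulated numbers are no measure of the overlap that shared samples bring among changed genes. The count highest in IKDC was 144 without cDC replicate 1, 154 without cDC replicate 2, 99 without IKDC replicate 1 and 95 without IKDC replicate 2. That in PDC was 118 without cDC replicate 1, 121 without cDC replicate 2 and 111 without PDC replicate 2. That in cDC was 86 without cDC replicate 1, 67 without cDC replicate 2, 169 without IKDC replicate 1 and 173 without IKDC replicate 2.

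**Figure D3:**
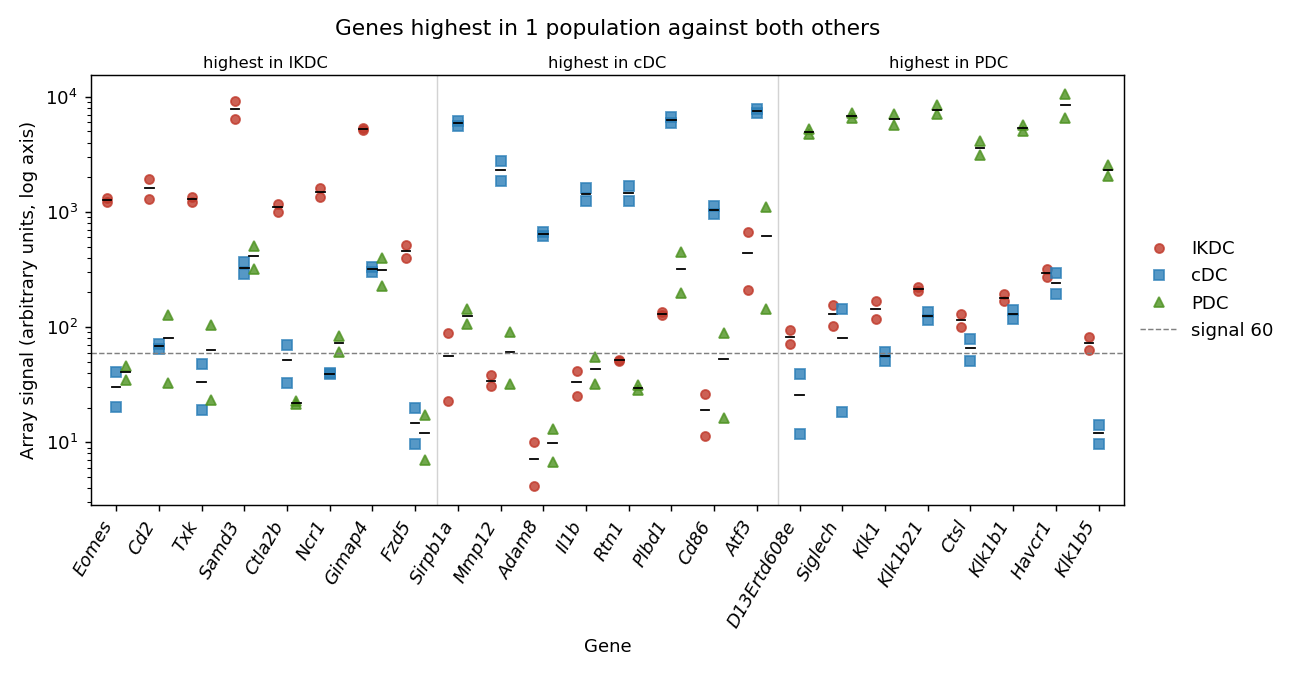
Array signal (arbitrary units, log axis) of the 8 leading genes highest in IKDC, cDC and PDC, in each IKDC (circles), cDC (squares) and PDC (triangles) sample, with the mean of the 2 samples as a bar and the signal minimum of 60 dashed. For each gene both samples of the named population lie above all 4 other samples.

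IKDC and PDC shared part of their differences from cDC. Haemoglobin Hba-a1, the kinase gene Fyn (2.92 ± 0.33 log2 units in IKDC and 2.97 ± 0.33 in PDC) and Car1 (at least 10.7-fold and at least 6.59-fold) were higher in both. Sirpb1a, Mmp12 and Csf1r (-3.98 ± 0.30 and -3.19 ± 0.30) were lower in both. With the mean of all probe sets of a gene in place of the brightest, Fyn reached limma adjusted p of 0.0679 in IKDC and 0.0697 in PDC, and Csf1r 0.162 in PDC. By limma 138 probe sets were higher in both populations and 267 lower in both, against 10.8 and 13.1 for independent lists of these lengths. The 267 lower in both are by definition the probe sets counted above as highest in cDC, and not a separate result. In 100 simulations of unchanged groups with the same cDC samples the means were 0.04 and 0.02. Almost nothing is called in those simulations, and they do not measure the overlap that shared controls bring among changed genes. Opposite calls numbered 23, with 23.7 for independent lists. Across probe sets the log2 differences correlated at 0.55, where shared controls alone gave 0.50 in the simulations, and their covariance was 0.387 against a simulated 0.125, a difference of 0.262. The simulated groups differ by noise alone, and the design sets their correlation. It is no measure for data in which populations differ. An observed correlation above or under the simulated one therefore does not decide how much is shared. With 1 sample left out of the observed and simulated values alike, the correlation was under the simulated one without cDC replicate 1 (0.615 against 0.667) or cDC replicate 2 (0.635 against 0.667). It was above it without an IKDC or PDC sample, least so without PDC replicate 2 (0.442 against 0.408). The covariance differences with 1 sample left out were 0.219 to 0.305. With 2 cDC samples each part of a split would hold 1, the controls were not split, and part of the excess in the overlap may come from them. Probe sets higher in both numbered 64 without cDC replicate 1, 79 without cDC replicate 2, 75 without IKDC replicate 1 and 69 without IKDC replicate 2. Those lower in both numbered 86, 67, 169 and 173 in the same order.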

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

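The tests of the repeat-named control were chosen only after its signals had been seen. A search of 33 control probe sets left out of the comparisons, in 2 populations, kept those with both samples above both cDC samples, and at 60 or more, on all 3 array types. Chance alone orders 2 against 2 samples so in 16.7% of cases per array type, or 11 of the 66 comparisons. The array types carry the same samples and do not repeat the test independently. The search kept 7, which is not above that number, and 6 of them are 3 parts of the 18S ribosomal RNA in both populations. The 18S ribosomal RNA controls had mean signals on U74A of 862.8 in IKDC and 924.8 in PDC against 423.3 in cDC at the 3' end, 473.1 and 368.4 against 188.4 in the middle, and 292.4 and 285.3 against 128.8 at the 5' end. The SD of the 2 samples was 95.04, 79.1 and 133 at the 3' end, 3.82, 79.7 and 76.7 in the middle, and 106, 118 and 24.3 at the 5' end. The transferrin receptor control at the 3' end had 77.45 in PDC against 60.6 in cDC, with SDs of 13.4 and 2.83.

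A control probe set named for the B1 repeat of the mouse genome was higher in cDC than in IKDC, by a ratio of 5.8 on U74A, 8.61 on U74B and 6.99 on U74C. Its ratio of cDC to PDC was 2.65, 3.35 and 3.07, and PDC lay between the other populations on each array type. Genomic DNA in the cDC samples would raise the B2 repeat control as well, and its highest ratio to IKDC over the 3 array types was 1.32 and to PDC 1.11, which argues against that source. The spiked CreX control had highest ratios of 1.07 to IKDC and 1.08 to PDC. Scaling to a common target removes the brightness of a whole array, so CreX cannot test that. A larger scaling factor on the cDC arrays would raise CreX, and these ratios argue against it for the mean of the 2 cDC samples. Those samples differed on U74A. CreX was 18679.8 and 8485.9 in cDC replicates 1 and 2, and the B1 control 2947.5 and 4819.9. Abundant cDC transcripts that carry the repeat or match its probes may account for the B1 difference. Its lowest ratio to IKDC of 5.8 does not decide, since no probe sequences are given in the sources used here. A difference between the populations themselves also stays open and was not tested.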

How the results depend on the processing

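None of the 122 called gene differences and 42 called list tests given in the text changed direction under the alternatives run for them, and 4 results that had not passed did. Other called probe sets were not checked for this. These were the log2 difference of Cd8a between PDC and cDC, which ranged from -0.657 to 0.475 with 1 sample left out (0.107 without PDC replicate 1), and 3 lists. Cytotoxic effectors in PDC versus cDC turned lower without cDC replicate 1 (adjusted p = 0.68) or PDC replicate 1 (adjusted p = 0.931), within a range from adjusted p = 0.393 to 0.931. NK receptors there turned without PDC replicate 1 (adjusted p = 0.656), with a range from adjusted p = 0.0557 to 0.656, and plasmacytoid genes in IKDC versus cDC without the filter (adjusted p = 0.727). The cause was not tested. Of 122 called gene differences 2 ended with a pseudocount of 1, 2 after quantile normalization, 7 without the intensity trend and 6 with the mean of probe sets. Of 42 called gene lists 7 ended with a filter at 200 and 12 with fry. At an adjusted p of 0.01 the counts were 626 (IKDC versus cDC), 396 (PDC versus cDC) and 533 (IKDC versus PDC), and 122, 112 and 127 probe sets were highest in IKDC, PDC and cDC, since a stricter threshold passes fewer. With 1 sample left out, which makes a lone sample vary like the other groups by assumption, they ranged from 593 to 1656, 327 to 719 and 493 to 869, those highest in IKDC from 95 to 246, in PDC from 111 to 173 and in cDC from 67 to 218, those higher and lower in both IKDC and PDC from 64 to 117 and from 67 to 218, and the correlation of both differences from 0.442 to 0.635, where unchanged groups gave 0.408 to 0.667. That correlation was 0.538 with a pseudocount of 64 and 0.557 after quantile normalization, and the cause was not tested. The correlation of unchanged groups is set by the design and is no measure for populations that differ. Gene lists called fell from 16, 14 and 12 to 1, 1 and 1 with an estimated correlation. Gene correlation above the preset 0.01 is not the whole reason. For plasmacytoid genes in PDC versus cDC the estimate was -0.00577, yet unadjusted camera p rose from 1.33e-35 to 0.000786. For conventional dendritic cell genes in IKDC versus cDC it was -0.0239, and unadjusted camera p rose from 2.4e-19 to 0.00195. The settings thus differ by more than the correlation, and the rest of the cause was not tested. The labels do not say whether equal replicate numbers mark a shared preparation. Deviations of same-numbered samples correlated at -0.0862 to 0.235, highest between cDC and PDC on U74A, so a shared part is not excluded. With a replicate block the counts were 1650, 1055 and 1223, against 1305, 849 and 1036 without it. With that block Actb in IKDC versus cDC (limma adjusted p = 0.00267) and H2-Ab1 in PDC versus cDC (limma adjusted p = 0.0335) passed, and the calls of the lineage factor list in IKDC versus cDC (adjusted p = 0.0591) and the sensing list in PDC versus cDC (adjusted p = 0.0527) ended. Neither quantile normalization nor median centring moved the share of higher calls by over 10 points, but leaving out 1 sample did, to between 35.8% and 55.9% (IKDC versus cDC, from 47.9%), 36.2% and 67.6% (PDC versus cDC, from 47.3%) and 36.4% and 56.9% (IKDC versus PDC, from 46.3%). Signal over background limits low genes most, and the minimum of 60 is least secure on U74C.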

Other observations

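Transcripts typical of exocrine pancreas were higher in IKDC than in cDC. Of 19 measured genes of a list drawn up afterwards, 7 rose and none fell by limma in IKDC, and 1, Cela3b, rose in PDC. Cpb1 and Prss2, which encode pancreatic proteases and were chosen after their values were seen, had signals of 1074 ± 390 and 818.5 ± 148 in IKDC, 357 ± 115 and 308 ± 127 in PDC, and 93.95 ± 18.7 and 49.95 ± 54.4 in cDC. Among the listed genes, Ctrb1 (chymotrypsinogen) stood at 1487 ± 83.1 in IKDC, 812 ± 142 in PDC and 531 ± 5.59 in cDC, and the lipase gene Cel at 719.9 ± 88.5, 379.6 ± 20.4 and 239 ± 40.2. The elastase genes Cela1 and Cela3b stood at 636 ± 174, 310.1 ± 102 and 243 ± 30.5 and at 358 ± 12.9, 119 ± 1.2 and 16.6 ± 0.919 in the same order, and Cpa1 at 438 ± 69.7, 165 ± 178 and 23.6 ± 19.2. In IKDC and PDC, Pla2g1b had 736 ± 139 and 671 ± 6.36, and Ctrl had 208 ± 72.5 and 199 ± 33.2. Neither passed against cDC by limma.

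The tests of scaling, of a common erythroid source and of IKDC RNA in PDC replicate 2 were chosen only after the result was seen, and those of the pancreas list and of low-signal noise before. The 19 measured pancreas genes had a raised median in IKDC. Their median log2 difference between IKDC and cDC, 1.44, lay at percentile 100 of 10000 matched random lists, whose 95th percentile was 0.307. Such lists draw genes independently, and the percentile takes no account of genes that move together. RNA of the neighbouring pancreas may be the source. Expression by the cells would raise the list alike, and the test cannot tell these apart. In PDC the median was 0.61, at percentile 100 too, with a 95th percentile of 0.28. That test does not cover the erythroid and immunoglobulin transcripts, whose source it leaves open. Hba-a1 had 12760 ± 987 in IKDC and 14590 ± 9230 in PDC, and Igha 5057 ± 1205 and 4544 ± 2729. Against a plain admixture, Clps was 97.3 ± 86.3 in IKDC and 308 ± 106 in cDC, Amy2a5 15.4 ± 15.2 and 91.3 ± 18, and Gcg 161 ± 118 and 335 ± 24, none called by limma. Both Amy2a5 means lay under 148.7, the highest unspiked bacterial control of any array type, and its difference is not secure. A further 7 listed genes on the arrays, Spink1 (5) and Rnase1 (40.4) among them, had IKDC means of at most 44.2. Of the 34 listed genes 26 were on the arrays and none is in the lists fixed earlier, and a sort that would remove such RNA is not given in the sources used here. Scaling between arrays is argued against for the erythroid part, whose list had a median log2 difference of 2.48 as deposited and 2.47 after quantile normalization. The median of all probe sets, -0.01, is no evidence, since scaling every array to one mean level holds it near that value. Probe sets with a signal like that of the erythroid genes were not compared separately. A common erythroid source at different shares cannot be told apart from several, because the ratio of IKDC to PDC signal above cDC spanned 3.74-fold over 6 genes, from Hba-a1 to Car2. Expression by the populations themselves stays open and untested.

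PDC replicate 2 lay nearer to an IKDC sample than to PDC replicate 1 on U74C alone, with correlations of 0.817 and 0.809, against 0.814 and 0.886 on U74A and 0.768 and 0.812 on U74B. Among probe sets with a mean of 500 or more an IKDC sample was nearer on 0 of the 3 array types, with correlations of 0.647 and 0.859 on U74C. That does not decide whether noise in low signals is the cause, because only U74C showed the pattern with all probe sets. Correlations with IKDC also fell on the other array types, on U74B to 0.257 and 0.292. IKDC RNA in that sample would raise the 167 genes highest in IKDC there, and as a set they were not higher. Their median log2 difference between PDC replicates 2 and 1 was -0.32, against -0.0127 over all genes, and 35.3% were higher in replicate 2. The semi-interquartile range across these genes, 0.44, exceeded the drop, which was therefore not taken to decide. That range is a spread across genes and not the uncertainty of the median. The 167 genes were chosen as lower in PDC, and all genes are not matched to them on signal. PDC replicate 1 had the higher low-end signal, with a 10th percentile on U74A of 9.9 against 4.1 in replicate 2. Such a difference could lower these genes in replicate 2 and hide added IKDC RNA. The lower Gapdh 3' to 5' ratio of PDC replicate 2 (3.19, against 6.0 in replicate 1) leaves a difference in amplification open, and no biological explanation was tested.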
